A study of Drosophila melanogaster with 4 samples.

How the data were processed

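Trimethylation of lysine 36 of histone H3 (H3K36me3), a mark of the bodies of transcribed genes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei of late-stage (last instar) larvae of the wild-type Drosophila melanogaster strain Oregon-R. The series has 4 samples, of which 2 are ChIP replicates made with an antibody named by its supplier (abcam) and 2 are the matching inputs, chromatin sequenced without immunoprecipitation. Per the labels' protocols, homogenised tissue was crosslinked with formaldehyde, chromatin was released from the nuclei by detergent and sonication, and antibody-bound fragments were collected on beads. Per the labels, each input served for the list of the ChIP replicate with the same number. Nothing in the labels says that the replicates came from separate collections of larvae, so the spread between them may be technical. The sex of the larvae is not given in the sources used here.

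Reads were aligned with Bowtie 0.12.7, per the submitters' processing notes. The authors deposited 1 list of enriched regions for each ChIP replicate and 1 combined list for the series, in GFF3 format, and these 3 lists are what was analysed here. Each entry gives the first and last base of a region, counted from 1, and a score. The score is the authors' deposited value, ranges from 0.0163 to 3.34 over the enriched regions of the 3 lists, and its unit is not given in the sources used here. It was therefore used to describe regions and as ranks, within a list or over regions matched between lists; 1 alternative compared mean scores within a list. The region caller, its thresholds, the way the input entered the calls and the way the combined list was made are likewise not given in the sources used here. A caller's threshold decides which weak regions are listed, and reads that map to several places are usually lost, so coverage of repeat-rich sequence is likely to be a lower limit. No read counts were used, so the sequencing depth is unknown and no counting interval is given.

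The sequence names and lengths in the file headers (2L, 23011544 bases; X, 22422827 bases; separate scaffolds such as 2LHet) are those of Release 5 of the genome, although no label names the build. The gene table at hand was of Release 6 plus ISO1 MT, so its coordinates were not used and no region was assigned to a gene. The planned comparisons over gene lists, annotation classes, position within genes and gene structure were not made for this reason. Covered length was measured over 13 sequences with 140 Mb in total: the large arms 2L, 2R, 3L, 3R and X, chromosome 4, the heterochromatic scaffolds 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet, and the unplaced sequence U. The replicate 2 list also holds 1 entry marked as depleted, which was kept out of the enriched regions. In the replicate 1 list and in the combined list the last region of 3L runs 444 and 584 bases past the stated end of the sequence, and these regions were cut at that end when covered bases were counted.

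The overlap of the replicates was measured as the Jaccard index (shared bases over all covered bases) and as the share of regions that overlap a region of the other list by at least 1 bp. Chance overlap was taken from 10000 circular rotations of a list along each sequence, which keep the widths of regions and gaps (two-sided p, smallest possible value 0.0002). X was set against the autosomal arms with a two-sided permutation test (100000 permutations) of the covered share of whole 1 Mb windows, with a 95% bootstrap interval of the difference (10000 resamples). Chromosome 4 was set against every stretch of its own length on the large arms, moved in steps of 100 kb. Both of these replace the planned Fisher exact tests over genes. The 2 Mb next to the centromere were compared with the rest of each arm by an exact sign-flip test over 5 arms. The clustering of regions was measured as the variance of the covered share of 100 kb windows against 10000 shuffles of the order of regions and of gaps within each arm. Windows, regions and arms are parts of 1 genome and not independent replicates, so these p-values describe the pattern along the sequence and not the spread between animals.

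The regions named as widest and highest scored follow a rule set before the data were examined. The rule named genes and, without gene models of the right build, the same regions by coordinate. It took the 5 widest regions found in both replicates and the 5 with the highest scores in each replicate. The widest were picked among regions matched 1 to 1, a condition that the rule did not state. Other stretches, scaffold regions and windows given by coordinate were chosen after their values were seen. A region was matched when it overlapped exactly 1 region of the other list and that region overlapped no other. The comparisons of the centromere-proximal 2 Mb, of clustering, of region widths and score ranks on X, of regions of 1 replicate alone on chromosome 4 (Fisher exact test) and of score ranks over matched regions (exact sign test) were added after the data were seen. Adjusted p-values are Benjamini-Hochberg values; those of region width are over 4 tests, the other 2 being of mean scores. The tests were also tried on simulated data. Of 100 pairs of independent simulated lists of 3623 regions on the large arms, the rotation test called 7 at p under 0.05. The window permutation test was tried on independent normal values for 22 and 95 windows. It called 5 of 100 simulations without a difference and 100 of 100 with a difference of 8 percentage points. Real neighbouring windows may not be independent. A difference of 8 percentage points lies outside the bootstrap interval found for X, -3.21 to 3.00, and smaller differences were not simulated. The clustering test called 0 of 20 randomly placed lists. Alternatives were a stricter score threshold at the median of each list, merging of regions less than 500 bp apart, a 50% reciprocal overlap, leaving out either replicate, the combined list in place of the replicates, and leaving out scaffolds. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1.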

Results

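H3K36me3 was mapped in 2 ChIP replicates from nuclei of wild-type larvae of the last instar, each with its own input. Coordinates are those of the files, whose sequence lengths are those of Release 5. The data are the authors' lists of enriched regions: 3785 regions in replicate 1, 3956 in replicate 2 and 3981 in the combined list. The regions covered 23.6 Mb in replicate 1 and 23.9 Mb in replicate 2, which is 16.9% and 17.1% of the 140 Mb of sequence. Typical regions were several kilobases wide, with a median width of 4869 bp in replicate 1 and 4606 bp in replicate 2, and the narrowest had 1301 and 1305 bp. Regions over 20 kb numbered 71 in each replicate and held 7.49% and 7.48% of the covered bases. The large arms 2L, 2R, 3L, 3R and X carried 95.7% of the regions of replicate 1 and 96.2% of those of replicate 2. With 2 replicates, no exact test of 1 sequence against another over the replicates can reach 0.05, so values are given as mean ± SD (n = 2).

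The first question was where in the genome of larval cells the mark lies. The large arms were covered for 19.4% ± 0.237 of their bases. Among them 2R had the highest share, 22.7% ± 0.329, and 2L the lowest, 17.3% ± 0.126. The share was 18.3% ± 0.189 on 3L, 19.9% ± 0.318 on 3R and 19.1% ± 0.216 on X. The differences of 2R and of 2L from each of the other arms were larger than the SD between replicates. Region density followed the same extremes in both replicates, with 35.2 and 37.1 regions per Mb on 2R and 26.9 and 28.4 on 2L.

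**Figure D1:**
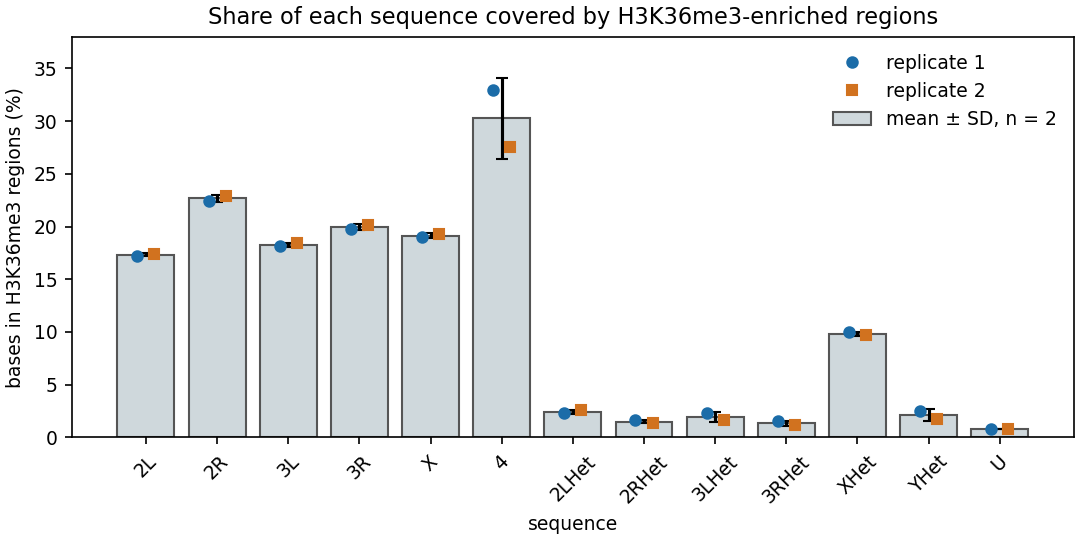
Share of the bases of each sequence (horizontal axis) that lay in H3K36me3-enriched regions (vertical axis, percent). Bars give the mean of the 2 replicates, error bars the SD, circles replicate 1 and squares replicate 2. Chromosome 4 stands highest at 30.3%, the large arms lie between 17.3% and 22.7%, and the heterochromatic scaffolds other than XHet lie below 2.6%.

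Chromosome 4, the small chromosome on which genes sit within heterochromatin, had the highest covered share of any sequence, 30.3% ± 3.85. It carried 78 regions in replicate 1 and 72 in replicate 2, or 57.7 and 53.3 per Mb. Of 1124 stretches of the same length on the large arms, 39 reached the share of chromosome 4, and the median of all stretches was 19.5%. The stretches start every 100 kb and overlap heavily, so they are not separate comparisons. The share of stretches below chromosome 4 was 96.5%, and it was 88.5% without replicate 1 and 98.4% without replicate 2. The scores of its regions were low within each list: the median was 1.21 in replicate 1 against 1.68 on the autosomal arms, and 1.10 against 1.63 in replicate 2. When only regions at or above the median score of their list were kept, 13.6% of chromosome 4 was covered and 48.8% of the large-arm stretches lay below it.

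The heterochromatic scaffolds carried few regions. Together their 9.28 Mb had 55 regions in replicate 1 and 51 in replicate 2, and 1.82% ± 0.283 of their bases were covered, against 19.4% on the large arms. Shares are of the full stated length, and reads that map to several places are usually lost. The shares of repeat-rich scaffolds are therefore likely to be lower limits. XHet stood apart with 9.83% ± 0.171, while 2LHet, 2RHet, 3LHet, 3RHet and YHet had means between 1.32% and 2.43%. The unplaced sequence U had 29 regions in each replicate and a covered share of 0.807% ± 0.0202. On YHet, sequence of the male-specific Y chromosome, 3 regions were found in both replicates: in replicate 1 they spanned bases 305615 to 307903, 326748 to 328383 and 336404 to 339182. A further YHet region, from 312084 to 314137, was listed in replicate 1 alone. On XHet the region from 76027 to 81839 in replicate 1 was matched by 76104 to 81688 in replicate 2, with a score of 2.21 and 2.04. Over all scaffolds together the median score was 0.817 in replicate 1 and 0.656 in replicate 2, but it was 1.75 and 1.57 on XHet, with 3 and 4 regions, and 1.45 and 1.22 on YHet, with 4 and 3 regions.

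X, the chromosome whose genes are dosage compensated in males, was set against the autosomal arms, and no difference in covered sequence was detected. The sex of the larvae is not given in the labels. Windows of 1 Mb were covered for 19.5% ± 6.74 on X (SD, 22 windows) and for 19.6% ± 7.08 on the autosomal arms (95 windows). The difference, X minus autosomes, was -0.148 percentage points (two-sided permutation p = 0.93), with a 95% bootstrap interval from -3.21 to 3.00 percentage points. Region widths were also alike in their medians, 4880 bp on X and 4976 bp on autosomal arms in replicate 1 and 4610 and 4710 bp in replicate 2. The mean log2 width differed by -0.03 in replicate 1 (permutation test, adjusted p = 0.371) and by -0.04 in replicate 2 (permutation test, adjusted p = 0.371). Scores, ranked among the large-arm regions of a list, were higher on X in replicate 2, with a mean percentile of 52.8 against 49.3 on the autosomal arms (two-sided permutation test, adjusted p = 0.006 over 2 tests). In replicate 1 the mean percentiles were 50.7 and 49.8 and did not pass the test (two-sided permutation test, adjusted p = 0.484). The tests of widths and of scores treat neighbouring regions as independent.

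Along the arms, coverage rose and fell over megabases, and the replicates traced a similar course. The most densely covered 1 Mb windows were 3R from 20000001 to 21000000 with 34.9% in replicate 1 and 36.2% in replicate 2, and 2R from 19000001 to 20000000 with a mean of 33.7%. The least covered were 2L from 14000001 to 15000000, with 3.61% and 3.62%, and 3L from 23000001 to 24000000, near the centromere, with 5.28% and 4.31%. The 2 Mb next to the centromere were covered less than the rest of the arm on 4 of 5 arms: 5.66% against 19.4% on 3L, 8.93% against 20.1% on X, 13.2% against 23.7% on 2R and 11.8% against 17.9% on 2L. On 3R they were covered more, 26.4% against 19.4%. The mean difference over the arms was -6.89 percentage points ± 8.23 (SD, n = 5), which did not pass an exact two-sided sign-flip test (p = 0.188, smallest possible p 0.0625).

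**Figure D2:**
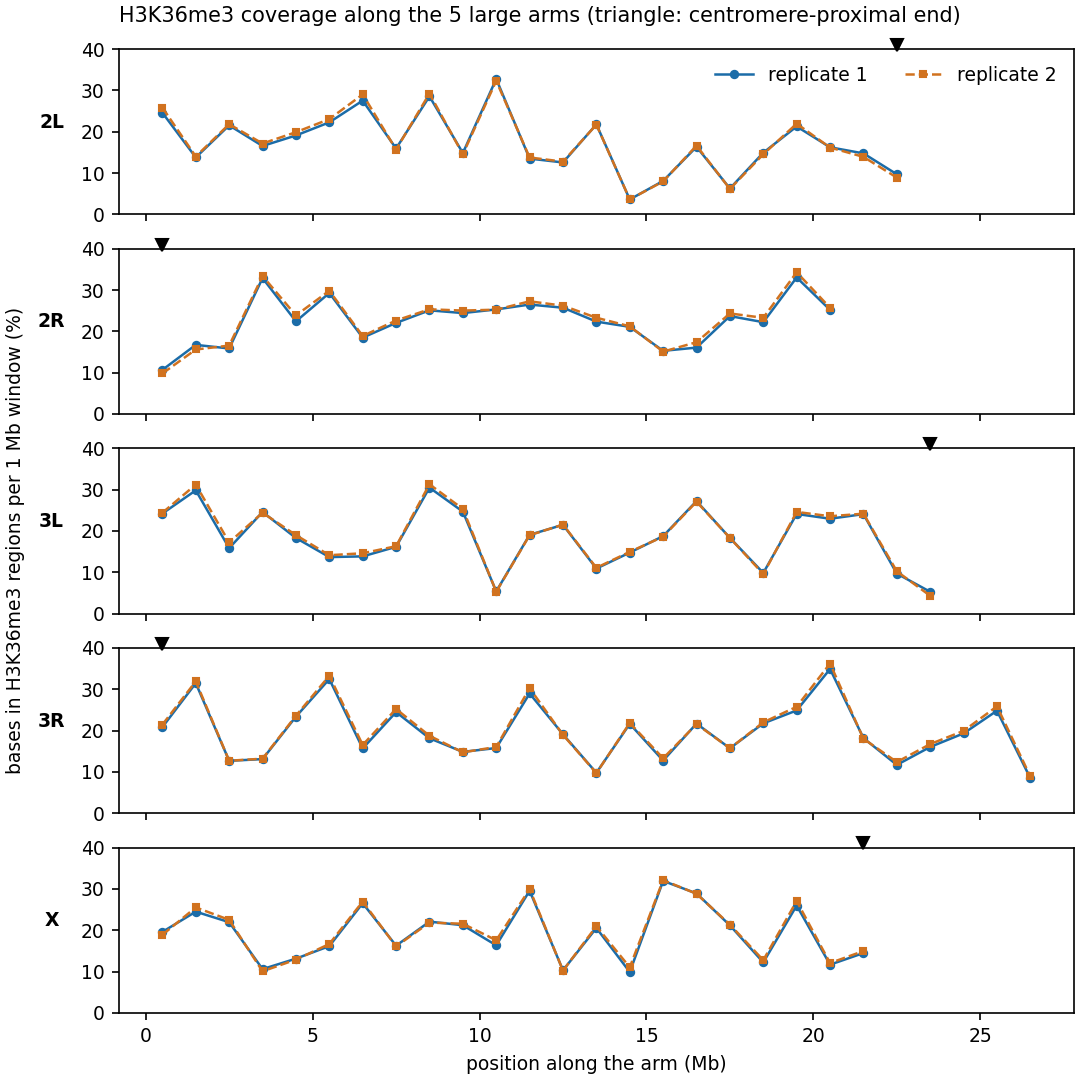
Percent of the bases of each whole 1 Mb window that lay in H3K36me3-enriched regions (vertical axis) against position along 2L, 2R, 3L, 3R and X in Mb (horizontal axis). Circles with solid lines are replicate 1, squares with dashed lines replicate 2, and triangles mark the end next to the centromere; replicate 1 runs from 3.61% on 2L to 34.9% on 3R and replicate 2 from 3.62% to 36.2%.

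Shuffling the order of regions and of gaps within each arm made coverage only slightly more even. The shuffled lists hold the same region widths and gap lengths, so clustering that lies in the gap lengths themselves was not tested. The SD of the covered share over 100 kb windows was 17.2 in replicate 1, against a shuffled median of 16.4. In replicate 2 it was 17.5 against 16.7. Of 1189 windows of 100 kb on the large arms, 220 had no covered base in replicate 1 and 220 in replicate 2, while 71 and 79 windows were covered for 50% or more. These counts were not set against shuffled lists. The variance of the covered share between windows was 1.10 times that of shuffled lists in replicate 1 and 1.11 times in replicate 2 (two-sided permutation p = 0.0002 in each, the smallest that 10000 shuffles can give). The gaps between neighbouring regions had a median of 6673.5 bp in replicate 1 and 5880 bp in replicate 2, and 18.6% and 20.0% of them were under 1 kb. The shuffles keep the gap lengths, so these values do not bear on the clustering test.

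The other question was how far the replicates share these regions. They shared 22.9 Mb, 96.7% of the covered bases of replicate 1 and 95.5% of those of replicate 2, with a Jaccard index of 0.925. Rotated lists gave a median Jaccard index of 0.108 and at most 0.219 (two-sided circular permutation test, p = 0.0002, the smallest that 10000 rotations can give). Of the regions of replicate 1, 3702 (97.8%) overlapped replicate 2, and of those of replicate 2, 3756 (94.9%) overlapped replicate 1, against rotated medians of 31.7% and 31.0%. For the 3315 regions matched 1 to 1, the boundaries differed by a median of 85 bp (quartiles 36 and 182 bp), and 2.35% of boundaries differed by more than 1 kb. Scores of the matched regions were correlated across regions with a Spearman rho of 0.959, and widths with 0.981. Regions are not independent replicates, so no p is given for these.

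The widest regions matched 1 to 1 lay on X, 3R, 2L and 2R. When no such match was required, the widest region found in both had 41700 bp in replicate 1 and 47844 bp in replicate 2. Neither is among the 5 regions named next. On X the region from 1750793 to 1791668 in replicate 1 had a mean width of 40.9 kb ± 0.0269 over both replicates. It was followed by 3R from 7032118 to 7069210 with 37.0 kb ± 0.173, 2L from 13363212 to 13395479 with 32.4 kb ± 0.123, 2R from 9738525 to 9770849 with 32.2 kb ± 0.12 and 3R from 20456913 to 20488050 with 31.2 kb ± 0.0198. Of the 5 regions with the highest scores in each replicate, 3 were the same. The region on 2R from 5453116 to 5464938 ranked 1 in replicate 1 and 3 in replicate 2, that on 3L from 6736693 to 6745440 ranked 3 and 1, and that on 3R from 20060652 to 20084934 ranked 5 and 2. The region on U from 8907358 to 8909722 ranked 2 in replicate 1 and 46 in replicate 2, and that on 3R from 6137247 to 6168128 ranked 4 and 18. In replicate 2 the regions on X from 8139181 to 8146067 and on U from 6384244 to 6389007 ranked 4 and 5, and their counterparts ranked 28 and 31 in replicate 1. Score rose with width within each list, with a Spearman rho across regions of 0.726 in replicate 1 and 0.753 in replicate 2.

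Regions found in 1 replicate alone were narrow and low in score. Replicate 1 had 83 of them with a median width of 1723 bp and a median score at percentile 4.54 of its list. Replicate 2 had 200, with a median width of 1645 bp and a median score at percentile 6.85. The regions found in both held 99.4% and 98.5% of the covered bases of replicates 1 and 2. On the large arms 54 regions were found in replicate 1 alone and 194 in replicate 2 alone. On chromosome 4 the balance was the opposite: 14 of 78 regions were found in replicate 1 alone and 0 of 72 in replicate 2 alone (two-sided Fisher exact test against the large arms, p = 2.13e-09). When a 50% reciprocal overlap was required, the numbers on chromosome 4 were 19 and 13 (two-sided Fisher exact test, p = 0.0069), so the count of 0 rests on the 1 bp overlap. From replicate 1 to replicate 2 the covered bases changed by -16.5% on chromosome 4 and by -19.8% on the heterochromatic scaffolds, and by 1.74% on the large arms. Among the scaffolds the change was -30.6% on YHet, -29.6% on 3LHet, -25.1% on 3RHet, -15.2% on 2RHet, -2.44% on XHet and 12.9% on 2LHet, and on U it was -3.48%.

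**Figure D3:**
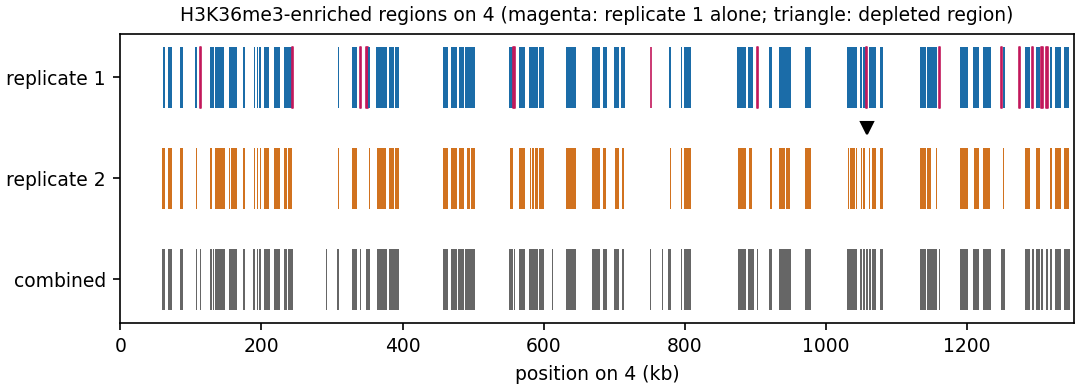
Map of chromosome 4 (horizontal axis, position in kb) with the H3K36me3-enriched regions of replicate 1 (top), replicate 2 (middle) and the combined list (bottom) drawn to scale. Magenta bars are the 14 regions of replicate 1 without a counterpart in replicate 2, outlined to remain visible, and the triangle marks the 1 entry that the replicate 2 list gives as depleted.

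The scores of all 3315 matched regions were also ranked within each replicate. On chromosome 4, 48 of 57 matched regions ranked lower in replicate 2 (exact sign test, adjusted p = 3.8e-07 over 5 classes of sequence), and their median percentile was 37.0 in replicate 1 and 23.7 in replicate 2. On the heterochromatic scaffolds 34 of 39 ranked lower (exact sign test, adjusted p = 4.05e-06), whereas on U 11 ranked lower and 14 higher (exact sign test, adjusted p = 0.69). On X, 370 regions ranked higher and 230 lower in replicate 2 (exact sign test, adjusted p = 6e-08), and on the autosomal arms 1304 ranked higher and 1282 lower (exact sign test, adjusted p = 0.69). The sign tests treat neighbouring regions as independent, and falls on chromosome 4 and the scaffolds can raise other ranks. With ranks among the 3194 matched regions of the large arms alone, 360 ranked higher and 240 lower on X. On the autosomal arms 1252 ranked higher and 1331 lower. Over 1 Mb windows, X against the autosomal arms had a two-sided permutation p of 0.00764.

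The combined list took in nearly all bases of both replicate lists. Of its 3981 regions, 3554 (89.3%) overlapped both replicate lists, 84 overlapped replicate 1 alone, 183 overlapped replicate 2 alone and 160 (4.02%) overlapped neither. It held 99.1% of the 24.7 Mb covered by at least 1 replicate. Its regions covered 33.9% of chromosome 4, 20.4% of the autosomal arms, 20.0% of X and 2.36% of the heterochromatic scaffolds. The regions found in neither replicate had a median width of 1187.5 bp and a median score of 0.323, against 5330 bp and 1.64 for those found in both.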

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

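Of 62 alternative values for 20 results, 49 kept their direction and their side of the threshold, or stayed within the limits set for values without a test, and 0 reversed. The window sizes, the alternatives for the sequence next to the centromere, for clustering and for regions of 1 replicate alone on chromosome 4, and score against width on the large arms were added after seeing the data. Restricting each list to regions at or above its median score moved 9 values, by construction for the counts: it left 1893 and 1978 regions and 16.1 and 16.7 Mb in replicates 1 and 2, covered 13.6% of chromosome 4 with 48.8% of large-arm stretches below it, covered 0.328% of the heterochromatic scaffolds, and left 1714 regions of the combined list found in both replicates and 44 in neither. Leaving out the scaffolds and U gave 23.4 and 23.7 Mb, and the combined list covered 2.36% of the heterochromatic scaffolds. Leaving out either replicate gave 88.5% (without replicate 1) to 98.4% (without replicate 2) of large-arm stretches below chromosome 4, so its rank rests partly on replicate 1. The excess of replicate 1 on chromosome 4 was 19 against 13 regions with a 50% reciprocal overlap, 9 against 0 above the median score and 11 against 0 after merging (Fisher exact p from 1.48e-07 to 0.0069). None of the 9 is among the 14 regions of the main comparison, whose highest score, 1.04, is under the replicate 1 median of 1.66. The 9 overlap replicate 2 regions that fell under the median of that list. This setting therefore does not check the 14, though it is counted among the 49. Mean scores on X against the autosomal arms, compared in place of ranks within each list although the unit is unknown, gave permutation adjusted p = 0.261 in replicate 1 and 0.002 in replicate 2, on the same side of the threshold as the ranks, a comparison also chosen after seeing the data. Like the ranks, it treats neighbouring regions as independent. Requiring widths of 1 kb or more removed no replicate region and so tested nothing, although its values are counted among the 49. The alternatives that need genes were not run, as no region was assigned to a gene. No paired analysis was possible because the input samples, which share replicate numbers with the ChIP samples, have no values in the files used here. Depth is unknown from these files, so what it limits was not tested.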

Other observations

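Large stretches of the arms carried no H3K36me3 region in either replicate. Stretches of 200 kb or more numbered 69, made up 16.5% of the large arms and were spread over 2L (19), 3R (15), 3L (14), X (11) and 2R (10). The longest lay on 2L from 14366082 to 15005199 (639 kb), on 2R from 15562268 to 16128808 (567 kb), on 3L from 18109955 to 18611391 (501 kb) and on X from 20396346 to 20894162 (498 kb). In the combined list 3, 2, 1 and 2 regions overlapped these stretches. Any overlap was counted, so some of these may be flanking regions that only reach over an edge. These stretches were singled out after their values were seen.

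The explanations below were tested after the patterns had been seen; the tests of overall calling in replicate 2, of chance on chromosome 4, of the minimum width and of the sequence called on X were chosen after their values were known, and the others before. A single test of the minimum width was replaced, after its result was seen, by 1 test for the narrower and 1 for the wider regions.

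The first pattern is the 14 regions on chromosome 4 found in replicate 1 alone at a 1 bp overlap, with 0 in replicate 2 alone, which became 19 and 13 at a 50% reciprocal overlap. Fewer calls in replicate 2 overall are argued against by the 194 regions of replicate 2 alone on the large arms, against 54 of replicate 1 alone, whereas chance stays open, because the Fisher exact p of 2.13e-09 was computed on the counts that drew attention to 4 and treats neighbouring regions as independent. At the 1 bp overlap, the scores and widths of the regions on 4 are also argued against as the whole source. Large-arm regions of replicate 1 matched to them in score and width were missing from replicate 2 in a median of 3 and at most 10 of 78 cases. The share of 10000 draws that reached 14, with the observed value counted in, was 0.0001, the smallest they can give. These draws likewise treat regions as independent and were set against the 14 that drew attention to 4. They are given for the 1 bp overlap alone. A difference between the libraries in repeat-rich sequence remains open as a candidate explanation, since covered bases fell further, or rose less, next to the centromere than in the rest on 4 of 5 arms; this is weak evidence, with an exact sign test p of 0.375, and while the covered bases of YHet, 3LHet, 3RHet and 2RHet fell by 30.6%, 29.6%, 25.1% and 15.2%, those of U and XHet changed by -3.48% and -2.44% and those of 2LHet by 12.9%. No biological explanation was tested, because the design gives the replicates the same strain, stage and antibody.

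The replicate 2 entry marked as depleted, on chromosome 4 from 1057217 to 1058962 with a score of -0.0865, lies within a region that replicate 1 lists as enriched, from 1057045 to 1059116 with a score of 0.567. It is the 1 depleted entry in the 3 lists.

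The second pattern is the higher rank of X regions in replicate 2. With ranks taken among the 3194 matched regions of the large arms alone, 18 of 23 X windows and 36 of 98 autosomal windows rose. The mean change was 2.48 percentile points higher on X (two-sided permutation p = 0.00764), so displacement by the regions on 4 and the scaffolds is argued against as the whole source. Chance stays open for X too, because this p was computed on the matched regions that drew attention to X. The covered bases of X grew by 1.61% from replicate 1 to replicate 2, more than those of 2L (1.04%) and 3L (1.47%) and less than those of 2R (2.07%) and 3R (2.28%); this does not bear on the ranks of regions matched 1 to 1, so it leaves open whether the calling of more sequence on X plays a part. The mix of male and female larvae in each replicate may matter for X and was not given in the labels, so this stays open and untested, as does any unequal scaling against input. The covered bases of YHet fell by 30.6%, but those of the autosomal scaffolds 3LHet and 3RHet fell by 29.6% and 25.1%, so the fall on YHet does not single out the Y chromosome. It was from 8.76 kb in 4 regions to 6.08 kb in 3 regions. Most of it is the 1 region of 2.05 kb listed in replicate 1 alone, so it says little about the mix of sexes.

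The third pattern is the 160 regions of the combined list that overlap neither replicate. Of these, 107 were narrower than the narrowest replicate region (1301 bp) and 53 were at least as wide. The narrowest region of the combined list had 1001 bp, and 137 regions of that whole list were narrower than 1301 bp. For the 107 and the 53 alike, a smaller minimum width in the combined list cannot be told apart from other changes of setting. No source used here gives a minimum width. The 53 exclude nothing, since a region can be wider in the combined list than in a replicate. The 131 of the 160 regions that lay on the large arms had more covered sequence beside them than random placement outside replicate regions gave. The rest were not tested. Of the 5 kb on each side of the 131, 22.5% was covered by replicate regions. In 1000 random placements on the same arms outside replicate regions the median was 6.10% and the highest value 10.1%. The placements also fall in the long stretches without regions, so the test cannot tell weak flanks of called regions from separate weak regions in densely covered neighbourhoods. A candidate explanation that fits these values is the pooling of reads bringing weak flanks of called regions over the threshold, which the lists alone do not test.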
